A study of Rattus norvegicus with 15 samples.

How the data were processed

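RNA came from the abdominal aorta of rats, with 15 libraries, 5 per group, and per the labels' protocols it was extracted with TRIzol, depleted of ribosomal RNA and made into libraries with NEB kits. The authors deposited 1 table per library with a signal value per transcript, a fractional abundance that is never negative. Whether it is FPKM or TPM is not given in the sources used here. Per the submitters' processing notes, limma was used (no version given) and the genome build was mm10, a mouse build, while the transcript IDs are those of rat. The aligner, assembler, annotation and abundance estimator are not given in the sources used here. The series text speaks of mice, the sample labels of rats, and the sample labels were followed. Groups and replicate numbers came from the labels. Each library is labelled as a rat of its group and was taken as a separate animal, which the labels do not state outright. If libraries shared an animal, the p-values would measure only the spread between samples, which may be technical. No pair of libraries looked like copies, the smallest SD of the log2 differences between any 2 libraries being 0.998.

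The tables of WKY and SHR list 41871 transcripts and those of SHR+Nef 41162, with 39097 in common. Tested on the values, every transcript in the WKY and SHR tables had a mean of at least 0.5 in WKY or SHR, and every transcript listed for all 15 libraries had a mean of at least 0.5 in SHR or SHR+Nef. The tables are thus already filtered by comparison, and a transcript with an SHR mean under 0.5 that is high in only 1 of the outer groups is missing from the other's tables. Low values were whole multiples of a step per transcript, as when 1 read sets the smallest value. If the values are FPKM, the step is inverse to depth, and relative to WKY replicate 1 it was 1.26 in SHR replicate 4 and 0.985 to 1.19 in the other 14 libraries. If they are TPM, no depth can be read from them. Depth in reads is otherwise unknown, so no counting intervals are given. An exact 0 can be a failed estimate.

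Since the values are not counts, no count test was run. Transcripts listed for WKY and SHR with a value of at least 1 in 5 or more libraries were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust options, two-sided), with the 3 groups in 1 model and 12 residual degrees of freedom. Transcripts not listed for SHR+Nef were fitted on the other libraries and joined before the variances were moderated. Adjusted p-values are Benjamini-Hochberg values over all transcripts tested in a comparison, and calls were made at 0.05. Differences on the log2(value + 1) scale understate the change of low transcripts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

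Locus sums and isoform shifts were added after the files were seen to list transcripts. For a shift, each assembled isoform's log2 value was set against the mean of the other isoforms of its locus, tested with limma, and combined per locus by Simes' method. The first test run was limma's diffSplice, which assumes 1 variance per locus. On simulated data for SHR vs WKY, with 3878 loci, 20 seeds and 100 loci per seed given a 4-fold shift in 1 isoform, 16.7% of its calls were false and 52.8% of the changed loci were recovered. With a variance per isoform 4.93% were false and 38.5% of the changed loci were recovered, and this test became the main one after both counts on the real data had been seen. The transcript test was also run on simulated data, with 29095 transcripts, 20 seeds and 200 changed transcripts per seed. For SHR vs WKY it recovered 66.5% of 4-fold changes with 6.31% false calls, and for SHR+Nef vs SHR 61.6% of 4-fold and 25.3% of 2-fold changes with 6.56% false calls. In both simulations the changes were set on the log2(value + 1) scale, where a 4-fold change in the value of a low transcript is smaller. The noise was normal, independent between transcripts and of equal spread in all libraries, whereas SHR replicate 4 stands apart in the real data. The rates hold for such simulated data only.

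The rule for named transcripts, fixed before the data were examined, takes those past adjusted p 0.05 whose groups do not overlap, with a mean of at least 1 in the higher group and a gene symbol, by size of change. The files do not pair the IDs with symbols, and 0 IDs could be matched to the gene table at hand, which has no Ensembl column filled. The symbol part was therefore dropped and at most 2 transcripts per direction were named, from 186 higher and 228 lower ones that met the rest of the rule between SHR and WKY and the 2 between SHR+Nef and SHR. For the same reason the gene lists and cell type markers fixed beforehand were not tested. The alternatives were limma without trend and robust options, array quality weights, median scaling, quantile normalization, no filter, a stricter filter, a pseudocount of 0.1, only the 2 groups compared, a minimum log2 difference of 1, a block for the replicate number and leaving out each of the 15 libraries.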

Results

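Transcript abundance was measured by RNA sequencing in 15 libraries from the abdominal aorta of rats, in 3 groups of 5. The groups were WKY, the normotensive Wistar Kyoto strain, SHR, the spontaneously hypertensive strain, and SHR given neferine, an alkaloid of the lotus seed (SHR+Nef). Treatment lasted 10 weeks, with double distilled water or neferine at 10 mg/kg per day. The deposited values are abundances per transcript on a scale that is not named, and their sums ranged from 496460 to 746274 per library. These sums are not read depths. The comparisons below ask how the aorta of SHR differs from that of WKY, and whether neferine shifts the aorta of SHR. The files identify transcripts by Ensembl rat IDs or by the locus and isoform number of an assembly (MERGE) and do not pair them with gene names, so at most 2 IDs are printed per direction and comparison, and pathways were not tested.

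The libraries separated by strain on the second principal component, which held 9.86% of the variance over 27097 transcripts. The first component, with 16.6%, set 1 library apart, SHR replicate 4, in which 8259 of the 39097 transcripts listed for all 15 libraries stood at 0, against 2560 to 3739 in the other 14. Its median rank correlation with the other SHR libraries was 0.536 across transcripts, against 0.665 to 0.717 in the other 14 libraries with their own groups. Transcripts are not independent replicates, so these coefficients only describe the libraries.

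**Figure D1:**
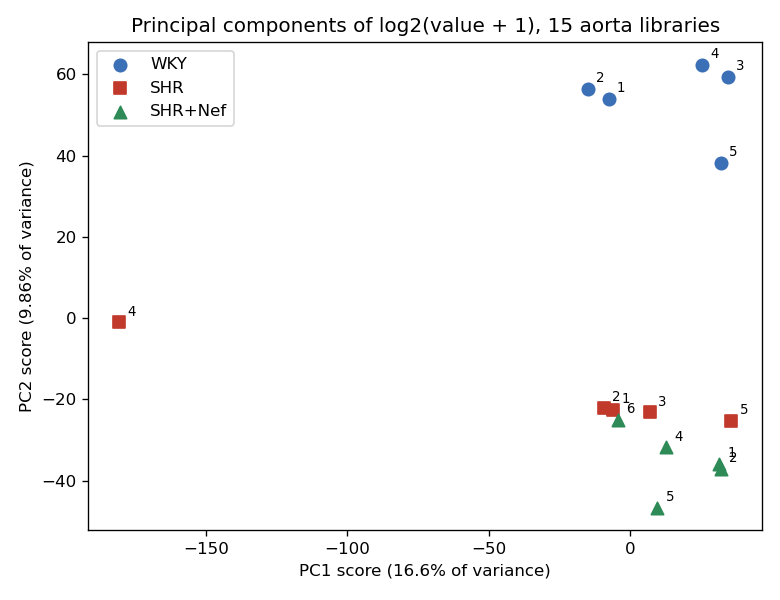
Scores of the 15 libraries on the first 2 principal components of log2(value + 1), with 1 point per library labelled by its replicate number and a colour and marker per group. The 5 WKY libraries lie between 38.2 and 62.4 on the second component, the SHR and SHR+Nef libraries lie at or below -1.0, and SHR replicate 4 lies at -180.9 on the first.

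Between SHR and WKY, the most widely separated transcripts were near 0 in one strain and abundant in the other. The assembled isoform MERGE.30995.1 was at 300.5 ± 75.4 in SHR and 0.773 ± 1.19 in WKY (SD, n = 5 each), and at 298.7 ± 38.1 in SHR+Nef (SD, n = 5). Its difference on the log2(value + 1) scale was 7.61 with a standard error of 0.32 (limma, adjusted p = 5.1e-09). MERGE.9062.3 was listed at 0 in all 5 WKY libraries and at 122.4 ± 41.2 in SHR (SD, n = 5; limma, adjusted p = 2.3e-09). In the other direction, ENSRNOT00000052292 was at 188.7 ± 113 in WKY and 0.697 ± 0.453 in SHR (SD, n = 5 each), a log2 difference of -6.63 with a standard error of 0.37 (limma, adjusted p = 9.7e-08). ENSRNOT00000061332 was at 19.3 ± 6.55 in WKY (SD, n = 5), was listed at 0 in 4 SHR libraries and stood at 1.07 in the other one, SHR replicate 3 (limma, adjusted p = 6.3e-05). All 4 kept their call under every alternative setting that tested them. The direction of ENSRNOT00000061332, which the SHR+Nef files do not list, is set by the listing described below.

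Of 29204 transcripts tested, 446 differed between SHR and WKY, 206 higher and 240 lower in SHR, with a median absolute difference of 1.51 log2 units. In 418 of the 446 the 5 SHR and the 5 WKY values did not overlap. Over all tested transcripts 2.94% did not overlap, where chance gives 0.794%. Assembled isoforms made up 315 of the 446 (70.6%) and 61.1% of those tested (Fisher's exact test across transcripts, two-sided, odds ratio 1.54, p = 2.47e-05). Between SHR+Nef and WKY the same shares were 65.0% and 61.0% (Fisher's exact test, two-sided, odds ratio 1.19, p = 0.123), which did not pass. Both tests treat isoforms of 1 locus as independent, though 25 loci held 2 or more isoforms called between SHR and WKY, so the p-values can be too small. Among the lower transcripts, 86 belong to the 109 tested ones that the SHR+Nef files do not list. Those 109 are listed through a WKY mean of at least 0.5 with an SHR mean under 0.5, so their direction is set by the listing. They entered the first Fisher test and not the second, so the 2 odds ratios are not on the same set of transcripts. The count was 175 among transcripts with values of at least 5 in 5 libraries. Which direction held more calls depended on the setting: without SHR replicate 4 there were 266 higher and 235 lower, with a pseudocount of 0.1 there were 229 higher and 196 lower, and among transcripts listed for all 15 libraries there were 194 higher and 137 lower.

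Summed per assembled locus, 184 of 10200 loci differed between SHR and WKY, 117 higher and 67 lower in SHR. With only the 2 groups in the model 83 were higher and 92 lower. That setting also summed isoforms not listed for SHR+Nef, whose direction is set by the listing and which the main sums leave out. The 2 pairs of counts thus rest on different isoforms, and their contrast cannot be put down to the model. With a minimum of 5 in 5 libraries 73 loci differed. Isoforms of 31 of 3878 loci shifted against the other isoforms of the same locus, and 25 of these 31 loci did not differ in their sum. The count was 7 with a minimum of 5 in 5 libraries, 18 without WKY replicate 3, 20 without SHR replicate 2 and 60 with diffSplice. At the locus with the smallest p, with 7 isoforms tested, 1 isoform stood at 0.287 ± 0.22 in WKY and 11.6 ± 2.11 in SHR, while another stood at 6.69 ± 1.42 in WKY and 0.826 ± 1.85 in SHR (SD, n = 5 each; limma with Simes combination, adjusted p for the locus = 1.5e-06). Ensembl transcripts are not tied to these loci in the files, so the sums hold assembled isoforms only. The main sums and shifts also hold only isoforms listed for all 15 libraries. Isoforms present in WKY with an SHR mean under 0.5 and not listed for SHR+Nef are left out, which removes lower ones. The balance of higher and lower loci, and the sums of loci with shifted isoforms, are therefore affected by the listing.

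**Figure D2:**
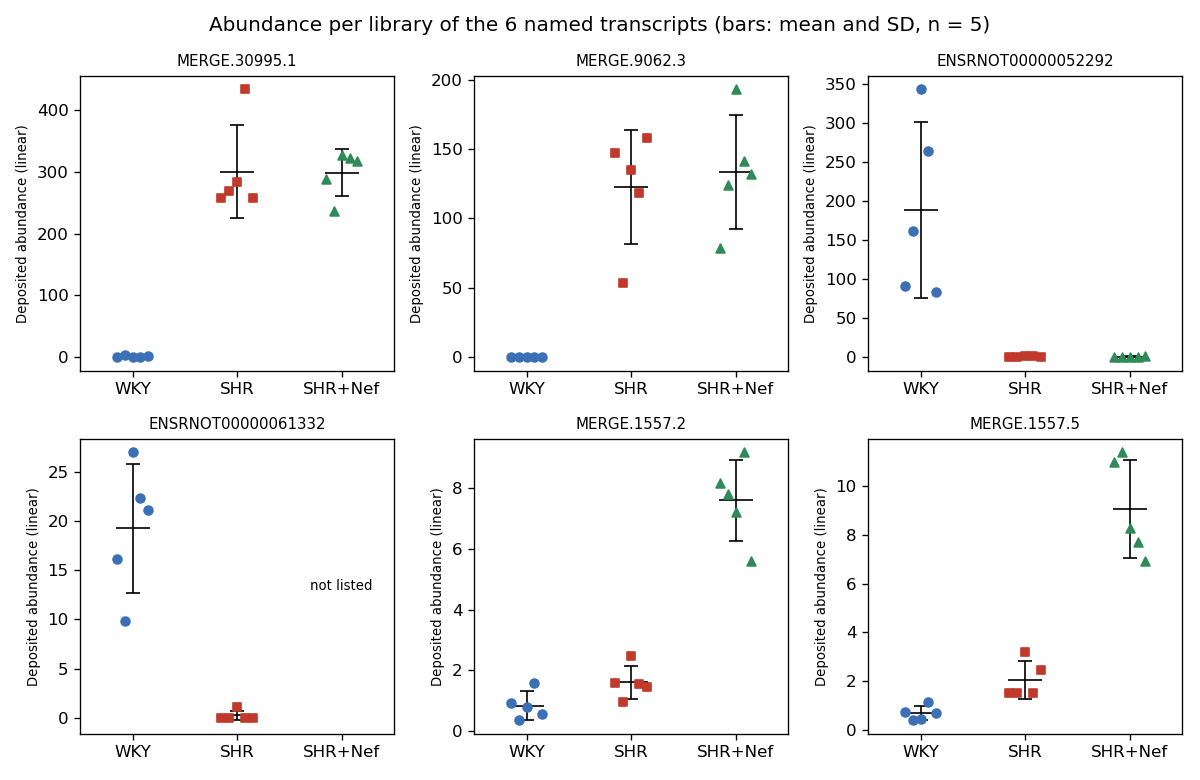
Deposited abundance per library, on linear axes, of the 6 transcripts named in the text, with points for libraries and bars for the group mean and SD (n = 5). The upper 3 panels and the lower left panel show the strain difference, with SHR+Nef at the level of SHR where it is listed, and the lower middle and right panels show MERGE.1557.2 and MERGE.1557.5, which are highest in all 5 SHR+Nef libraries.

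Between SHR+Nef and SHR, 2 of 29095 transcripts differed, both higher with neferine and both isoforms of 1 assembled locus, and 0 were lower (limma; 1792 had an unadjusted p under 0.05, and the smallest adjusted p of a lower one was 0.0879). The 2065 transcripts listed only for SHR+Nef did not enter the test, so a rise from a low level in SHR can be missed among them. Of these, 473 had a mean of at least 1 in SHR+Nef, and 36 of the 473 were at 1 or more in 4 or 5 of the libraries. Without SHR replicate 5, 2866 had an unadjusted p under 0.05. The 2 groups did not overlap in 315 transcripts, 1.08% of those tested, where chance gives 0.794%. MERGE.1557.2 was at 1.60 ± 0.555 in SHR and 7.59 ± 1.33 in SHR+Nef, and MERGE.1557.5 was at 2.06 ± 0.769 in SHR and 9.07 ± 2.01 in SHR+Nef (SD, n = 5 each). Each difference was 1.73 log2 units with a standard error of 0.21 (limma, adjusted p = 0.01), and in both all 5 SHR+Nef libraries lay above all 5 SHR libraries. In WKY the 2 isoforms were at 0.84 ± 0.463 and 0.698 ± 0.293 (SD, n = 5), so the level under neferine lay further from WKY than that of untreated SHR. The other 3 isoforms of the locus did not pass, with adjusted p of 0.53, 0.78 and 0.67 (limma). The locus sum was 4.24 ± 1.58 in WKY, 8.73 ± 3.45 in SHR and 29.99 ± 2.54 in SHR+Nef (SD, n = 5 each), and was the 1 locus sum of 10200 that differed between SHR+Nef and SHR (log2 difference 1.73, standard error 0.23, limma, adjusted p = 0.024). The 2 isoform calls ended with a pseudocount of 0.1 (0 called, 1698 with an unadjusted p under 0.05, limma) and with a minimum of 5 in 5 libraries (0 called, 681 with an unadjusted p under 0.05, limma). They also ended with the replicate block, given further below. The log2 differences of MERGE.1557.2 and MERGE.1557.5 were 2.22 and 2.13 with the pseudocount of 0.1 and 1.73 each with the minimum of 5. Next by p, and not passing, was an Ensembl transcript at 0.0114 to 0.0143 in the 5 SHR libraries and 23.5 to 29.8 in the 5 SHR+Nef libraries (log2 difference 4.77, standard error 0.70, limma, adjusted p = 0.071). It was at 23.2 in WKY replicate 5 and at 0.0113 to 0.0128 in the other 4 WKY libraries. Its low values in SHR and WKY varied between libraries as the step of 1 read did, so they stand at the floor. With an SHR mean under 0.5 it is listed for all 15 libraries only through WKY and SHR+Nef means of at least 0.5. The direction of its difference with neferine is therefore set by the listing. After it came a transcript at 1.90 to 2.99 in SHR and 0.297 to 0.695 in SHR+Nef, with a log2 difference of -1.17, and one at 0.571 to 0.80 in SHR and 3.05 to 7.35 in SHR+Nef, with a log2 difference of 1.91 (limma, adjusted p = 0.088 each). In WKY the last of these was at 4.08 in replicate 3 and at 0.604 to 0.782 in the other 4 libraries. These 3 were singled out after their values were seen. With only the 2 groups in the model MERGE.1557.5 did not pass (limma, adjusted p = 0.062), and 4 transcripts were then called. The count was 5 without SHR replicate 1, and 4 without SHR replicate 2 or SHR+Nef replicate 1, 2 or 5. Apart from the replicate block, given further below, the call of the locus sum ended with median scaling, with the pseudocount of 0.1, and without SHR replicate 1, 2 or 4 or SHR+Nef replicate 1, 4, 5 or 6, with adjusted p from 0.053 to 0.13 (limma) and log2 differences from 1.65 to 1.84. Isoform shifts were found at 0 of 3878 loci (limma with a variance per isoform; 227 had an unadjusted p under 0.05, and diffSplice, which assumes 1 variance per locus, called 9).

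No transcript was called as moved back: 0 were called both between SHR and WKY and, in the opposite direction, between SHR+Nef and SHR, and 0 in the same direction (limma). On simulated data the test of SHR+Nef vs SHR recovered 61.6% of 4-fold and 25.3% of 2-fold changes, so transcripts that moved back can be missed. With an unadjusted p under 0.05 in both comparisons, 440 had differences of opposite sign, 951 without SHR replicate 5 and 157 with a minimum of 5 in 5 libraries. The 2 comparisons share the SHR libraries, which by itself gives opposite differences. The listing gives them too, since a transcript listed for all 15 libraries with an SHR mean under 0.5 has means of at least 0.5 in WKY and SHR+Nef. Splitting the SHR libraries, as below, removes the first of these effects and not the second. The 2 sets of differences correlated at -0.457 across 29095 transcripts, against a mean of -0.573 over 100 simulated sets of unchanged groups, and their covariance was -0.124 against a simulated mean of -0.128. The simulated correlations ranged from -1 to 0.056 and the simulated covariances from -0.212 to 0.006. Such wide ranges leave little that the comparison of means can decide. With separate SHR libraries for each comparison, 3 for the first and 2 for the second, the covariance averaged 0.001 over the 10 splits and lay between -0.015 and 0.02. Without SHR replicate 4 it averaged 0.011 over 6 splits of 2 libraries each and lay between 0.002 and 0.025. Without SHR replicate 1, 3 transcripts were called in opposite directions, and without SHR replicate 5, 1 was.

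**Figure D3:**
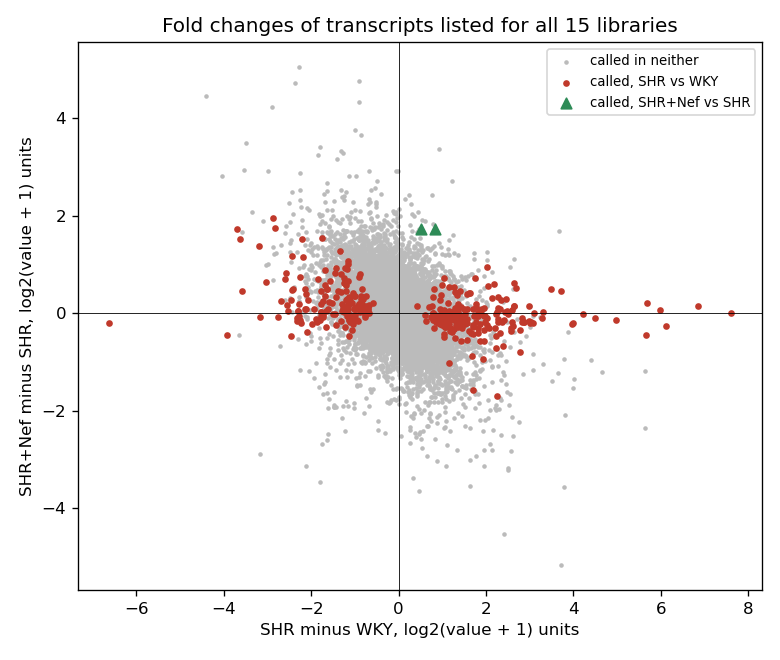
Difference of SHR from WKY (horizontal axis) against difference of SHR+Nef from SHR (vertical axis), in log2(value + 1) units, for the 29095 tested transcripts among those listed for all 15 libraries, with 1 point per transcript. Transcripts called between the strains lie along the horizontal axis, the 2 called with neferine are the triangles, and the slope of the grey cloud goes with the SHR libraries that both axes share.

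Between SHR+Nef and WKY, 377 of 29095 transcripts differed, 238 higher and 139 lower in SHR+Nef (limma). The count was 680 with array quality weights and 180 with a minimum of 5 in 5 libraries. Transcripts missing from either set of files were not tested here: those not listed for SHR+Nef, which removes lower ones, and the 2065 listed only for SHR+Nef, which removes higher ones. Among the transcripts listed for all 15 libraries, 239 were called in the same direction in both strain comparisons, 155 higher and 84 lower, and 0 in opposite directions (limma). Independent lists would share 1.59 higher and 0.65 lower ones, and simulated unchanged groups that share the WKY libraries reached at most 11. With the WKY libraries split between the comparisons, 56 to 80 transcripts were called in both.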

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

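The depth test of SHR replicate 4 was chosen after its values were seen. The groups of 5 were searched for a library far from the rest in 32 sets of values, of which chance would pick out about 5%. SHR replicate 4 stood apart in its summed abundance (746274), in its transcripts at 0 (8259), in its median rank correlation with its group (0.536) and in MERGE.30995.1 (434, the other SHR libraries lying lower). WKY replicate 1 stood apart in the share of its sum held by its 10 most abundant transcripts (27.1%), and SHR replicate 3 in ENSRNOT00000061332 (1.07, with the other SHR libraries at 0). Outside the comparisons, 2065 transcripts were listed only for SHR+Nef. Of these, 473 had an SHR+Nef mean of at least 1, of which 166 reached 1 in 1 library alone, and 7 were at 1 or more in all 5. The highest mean of the 7 was 2.27 ± 0.427 (SD, n = 5), and the highest of the 473, at 180.6, came from 1 library at 903 with the next at 0.00754. The 2065 are not listed for SHR or WKY, so no values of those groups were at hand to compare.

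For SHR replicate 4, a label from the other strain is argued against: on 468 transcripts called between SHR+Nef and WKY without SHR libraries, its median position was 0.86, where 0 is the WKY mean and 1 the SHR+Nef mean, and the other SHR libraries lay at 0.89 to 0.93. A lower effective depth stays open. Such a library may still lie close to its group among abundant transcripts, but its spread there was 1.42 times the highest of the other 14 libraries, between the bounds set for and against that explanation (1 and 1.5). No biological explanation was tested, since the labels give nothing that sets this rat apart.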

How the results depend on the processing

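Restricting to transcripts listed for all 15 libraries, the locus tests, the sum of MERGE.1557 by its own ID and diffSplice were chosen after the data were seen. The 6 named transcripts kept their direction in all 155 alternative values, which for ENSRNOT00000061332 is set by the listing, and their call in 148. The 7 lost calls were those of MERGE.1557.2 and MERGE.1557.5 with neferine, with adjusted p up to 0.26 (limma). Between SHR and WKY, the calls were 175 with the stricter filter, which tests fewer transcripts, and 326 to 501 with 1 library left out. For SHR+Nef against WKY they were 180 with the stricter filter, 680 with array quality weights and 256 to 540 with 1 library left out. For SHR+Nef against SHR they were 0 with the stricter filter (681 with an unadjusted p under 0.05, limma), 0 with the pseudocount of 0.1 (1698), 4 with only the 2 groups compared, of which 1 was among the 2 main calls, and 2 to 5 with 1 library left out, highest without SHR replicate 1. Transcripts called as moved back numbered 0 in every setting except without SHR replicate 1 (3) and SHR replicate 5 (1), so from 0 to 3.

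Locus sums called between SHR and WKY fell to 73 with the stricter filter. With neferine they were 0 with median scaling (649 with an unadjusted p under 0.05, limma) and with the pseudocount of 0.1 (614), 3 without a filter, 2 with the stricter filter, 3 with only the 2 groups compared and 0 to 3 with 1 library left out, at 0 without SHR replicate 4 (529) and without SHR+Nef replicates 1 (543), 4 (516) or 6 (688), at 2 without WKY replicate 5 or SHR+Nef replicate 2, and at 3 without SHR replicate 5. The sum of MERGE.1557 kept its direction throughout. Loci with shifted isoforms between SHR and WKY were 7 with the stricter filter, 60 with diffSplice, of which 25 were shared with the 31, and 18 to 26 with 1 library left out. With neferine they were 9 with diffSplice. Other causes were not tested. The planned gene lists were not run. Depth is unknown, which limits what a 0 can show.

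Deviations of same-numbered libraries from their group means correlated at -0.07 to 0.09 across transcripts, so the numbers do not pair the libraries. Among the same-numbered pairs, only WKY replicate 5 found its best match in the other group under its own number (SHR replicate 5, correlation 0.09). With the replicate block the calls were 233 between SHR and WKY, 0 between SHR+Nef and SHR (1906 with an unadjusted p under 0.05, limma) and 164 between SHR+Nef and WKY. The block left 0 locus sums called with neferine (711 with an unadjusted p under 0.05) and 11 loci with shifted isoforms between the strains. With it the sum of MERGE.1557 had a log2 difference of 1.78 with neferine (limma, adjusted p = 0.36). MERGE.1557.2 and MERGE.1557.5 had log2 differences of 1.88 and 1.85 (limma, adjusted p = 0.14 and 0.18).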

Other observations

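The hypotheses below were tested on the data in which they were seen. How often other groupings of the libraries give such counts was examined in 100 splits into groups of 5, the real one included.

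Of the 184 loci called between SHR and WKY, 18.5% had another called locus 2 to 10 numbers away, against a median of 9.78% over 10000 random draws among the 10200 tested. At 11 to 50 numbers away the share was 44.6% against 35.3%, and at adjacent numbers it was 6.52% against 1.09%, the widest ratio of the 3 distances (one-sided permutation p = 0.02 and 0.001, adjusted 0.02 and 0.003). Pieces of 1 gene numbered next to each other were predicted to give an excess only at adjacent numbers. The share at 2 to 10 numbers was above the middle 95% of the draws, which ended at 15.8%. A gene in more than 2 pieces would also give an excess there, so the test cannot decide and this explanation stays open. That loci of shared chromosome segments differ together may be a biological reading, but the bound set beforehand was worded loosely: read as a share above every draw it was not met, since the highest draw reached 25%, and read as a p under 0.05 it was met (one-sided permutation p = 0.005, adjusted 0.007), so this stays open. Whether numbers follow chromosome position was not shown. Deviations of loci correlated at a mean of 0.08 at adjacent numbers, 0.063 at 2 apart, 0.049 at 5, 0.054 at 10, 0.032 at 100 and 0.047 at 1000. These means were highest at adjacent numbers but did not fall steadily with distance, and they were not tested.

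Of the transcripts listed for all 15 libraries, 40 were at 10 or more in 1 library and under 0.5 in the other 14. All 40 were high in an SHR library, 18 of them in SHR replicate 4 and 11 in SHR replicate 5, but an isoform high in 1 WKY or 1 SHR+Nef library alone is not listed for all 15, so the absence from those groups follows from the listing, and 58 transcripts listed only for SHR+Nef were at 10 or more in 1 SHR+Nef library and under 0.5 in the other 4. Reads moved between isoforms of 1 locus are a candidate explanation: in 13 of the 29 that have another listed isoform (44.8%, exact 95% binomial interval 26.4 to 64.3) the locus sum stayed within 2-fold of its median in the other libraries. This lies between the bounds set beforehand, so the values leave it open. No biological explanation was tested.

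Among the splits, 1 of 100, the real one, called as many transcripts between SHR and WKY (446, the highest other 10), and likewise between SHR+Nef and WKY (377, the highest other 10), for locus sums between SHR and WKY (184, the highest other 11) and for shifted isoforms between them (31, the highest other 5). This argues against chance for these counts, at the smallest share that 100 splits can give. The 446 include 86 of the 109 tested transcripts that the SHR+Nef files do not list, and their listing favours the real split in advance. Between SHR+Nef and SHR, 31 of 100 splits called as many transcripts (2, the highest other 5) and 29 as many locus sums (1, the highest other 3), so chance cannot be excluded for these 2 neferine counts. For shifted isoforms the real count was 0 (the highest other 4; limma, 227 with an unadjusted p under 0.05, and 9 called by diffSplice), so all 100 splits had to call as many and the comparison shows nothing.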
